A study of Homo sapiens with 29 samples.

How the data were processed

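Gene expression was measured by poly-A RNA sequencing in human primary bronchial epithelial cells differentiated at an air-liquid interface on culture inserts. Single compounds or mixtures had been applied to the apical surface in acetone, and the labels give 48 h as the longest exposure. The 29 libraries fall into 7 groups, named here by compound and dose in µg/ml: acetone alone (5 libraries) and 4 libraries each of benzo[a]pyrene at 10 (BAP10) and 100 (BAP100), benzo[a]anthracene at 500 (BAN500), phenanthrene at 100 (PHE100), coal tar extract at 1500 (CTE1500) and a simulated air mixture at 250 (AM250). Each library's group came from its title. The series text states 4 replicates, while the acetone group held 5 labelled libraries, and all 5 were used.

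The deposited files hold 1 normalized signal value per gene and library, made by the authors as read counts divided by 1 size factor per library. No file header states this unit. It was read from the values: in each library every value is a whole multiple of 1 step, and 100% of the values came out whole within a tolerance of 0.001 of a read. Per the submitters' processing notes, cutadapt 1.8.1, Bowtie2, TopHat2 2.1.1, featureCounts, Subread 1.6.0 and DESeq2 1.26.0 were used with the genome build GRCh38. The role and order of each tool, the annotation release, the strand setting and any filter are not given in the sources used here. The size factors of the 25 libraries outside AM250 matched median-of-ratios factors computed over those 25 libraries alone, whereas the factors of the 4 AM250 libraries matched those computed over all 29. The AM250 values had therefore been scaled in a separate run, and the largest difference between the 2 scales was 1.88%, or 0.027 on the log2 scale.

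Whole reads were recovered from the values and divided by median-of-ratios size factors computed over all 29 libraries, which put every library on 1 scale. Recovered reads in genes ranged from 28.02 to 46.4 M (mega) per library, and these totals set the precision for low genes. The files list 60504 genes, of which 39566 had a read in any library. A gene was tested when its value reached 10 in at least 4 libraries, which left 18581 genes. GRCh38 coordinates were taken from the GENCODE v29 annotation by gene identifier. Gene symbols were taken by gene identifier from a separate list of gene names, whose release is not given here. In all, 68.1% of the listed identifiers were given a symbol. Older symbols in the gene lists were matched through RefSeq synonyms.

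The test was limma (3.58.1, in R 4.3.3) with a mean-variance trend on log2(value + 1), fitted to all 29 libraries with 1 coefficient per group and no covariate, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The design written before the data were examined named edgeR's quasi-likelihood test on counts. The deposited unit was not counts, so the limma test, with the filter above, became the main one and edgeR (4.0.16) on the recovered reads an alternative. That count test called 443 genes for BAP10, 8 for BAP100, 451 for BAN500, 665 for PHE100, 945 for CTE1500 and 9044 for AM250 against acetone. Fold changes are on the log2(value + 1) scale and understate the change of low genes. Errors of means are SDs between libraries, errors of log2 fold changes are standard errors, and intervals are 95% intervals of the limma fit. Each treatment was compared with acetone in 6 comparisons, and 5 comparisons were made between treatments. An F test over the 6 treatment coefficients asked whether a gene differed in any treatment.

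The genes named in the text followed a rule fixed before the data were examined. For each treatment against acetone, part (a) took the 8 genes with the largest rise and the 8 with the largest fall among genes with a symbol, a mean CPM of at least 1 in either group, an adjusted p under 0.05 and every treated library on the same side of every acetone library. Part (b) took up to 3 members of each called gene list with the smallest p in the direction of the list. Part (c) always took CYP1A1, CYP1B1, AHRR, TIPARP, NQO1, ALDH3A1, HMOX1, CDKN1A, MDM2 and GDF15. Between treatments, part (a) took 5 genes in each direction and part (c) was kept. Genes of the Y chromosome and XIST stayed in the fit and in the counts and were left out of all genes named and of the tables of genes.

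The gene lists, fixed before the data were examined, were AHR targets, NRF2 targets, p53 targets, DNA repair and damage signalling, cell cycle, inflammatory cytokines, interferon response, unfolded protein and amino acid response, heat shock, cholesterol synthesis, retinoid metabolism, cell junctions, mesenchymal and matrix remodelling, immediate early and AP-1, mitochondrially encoded RNA and ribosomal proteins. The marker lists covered ciliated, club and secretory, goblet, basal, squamous, ionocyte, neuroendocrine, fibroblast, endothelial and leukocyte cells. Of the 27 lists, 26 could be tested, since the files list 37 mitochondrial genes with 0 reads in any library. The symbol CCDC39 was not matched and was left out. The results of 1 further list and of 1 gene that the rule names are not given, though both are in the counts. Lists were tested with camera of limma at a preset correlation of 0.01 with Benjamini-Hochberg adjustment over the lists of 1 comparison. Beside it were run camera with an estimated correlation and fry, which tests whether the genes of a list move, on balance, 1 way, and which compares a list with no other genes. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. Some lists share members, so their calls are not separate evidence. NQO1 is in AHR and NRF2 targets, and ALDH1A3 in AHR targets and retinoid metabolism. SLC7A11 is in NRF2 targets and in the unfolded protein and amino acid response.

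Similarity of responses was measured across genes as Pearson and Spearman correlations and the covariance of log2 fold changes against acetone. Beside them stand the values from 100 simulated pairs of unchanged groups against the same acetone libraries, and from 10 splits of the acetone libraries into 2 and 3 used in both directions, so that the 2 comparisons shared none.

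The calculations were tested on simulated data made from the means and spreads of these libraries. For 4 libraries against 5, simulated on BAP10 and acetone with 18162 genes, limma called 2% of genes changed 1.25-fold, 30% of those changed 1.5-fold, 60% at 2-fold and 90% at 4-fold, with 1 false call. Simulated on CTE1500 and acetone with 18148 genes, the shares were 8%, 44%, 72% and 96%, with 4 false calls. With no gene changed, 0 of 18170 simulated genes passed with limma, and an added GC trend gave 3305 calls, which fell to 0 after the trend was removed. The added trend was a straight line on GC content, the same in every BAP10 library, so its removal was fixed in advance. It does not test whether removal handles real trends or spares true changes. At each fold 50 genes were changed, and every gene was drawn independently of the others. The changed genes were taken only from those above a minimum mean of reads, so the shares do not cover the lowest genes tested. Differences between libraries that many genes share were left out, so these shares and false calls need not hold for the real libraries.

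Alternatives fixed before the data were examined were DESeq2 (1.42.0), edgeR with RLE size factors, no filter on low values, a fit to the 2 groups compared alone, the replicate number as a block, limma voom with library weights, leaving out each library in turn, and an estimated correlation for lists. Those chosen after seeing the data were edgeR with TMM, pseudocounts of 0.5 and 5, the values as deposited, TMM factors, leaving out the AM250 group, and removal of each library's trend on GC content and gene length, with and without the replicate block. GC content and length were known for 99.2% of the tested genes. Replicates of a group were also compared by a chi-square test of their counts, and no pair fell within sampling noise, the smallest chi-square per degree of freedom being 16.5.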

Results

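RNA sequencing measured gene expression in bronchial epithelial cells grown from human primary cells and differentiated at an air-liquid interface, after apical exposure to single compounds, mixtures or the acetone vehicle. The acetone group held 5 libraries and each of the 6 treatments 4. Reads in genes per library (M, mega) averaged 38.2 ± 6.51 M (SD, n = 5) for acetone, 35.3 ± 4.11 M (n = 4) for BAP10, 41.3 ± 4.87 M (n = 4) for BAP100, 34.9 ± 2.89 M (n = 4) for BAN500, 32.8 ± 2.09 M (n = 4) for PHE100, 32.8 ± 2.1 M (n = 4) for CTE1500 and 36.7 ± 7.72 M (n = 4) for AM250. Correlations of log2 values between replicates of a group ranged from 0.958 to 0.981. The labels call the libraries replicates and do not say that they came from separate donors or cultures, so p-values measure only the spread between these samples, which may be technical. All values are normalized reads per gene, as mean ± SD between libraries. Folds come from means of log2 values and can differ from the ratio of the printed means, most where libraries of a group differ widely. Adjusted p-values come from limma with Benjamini-Hochberg adjustment. The strand setting of the counting is not given in the sources used here, so antisense and overlapping genes such as CERS3-AS1, C1orf50-AS1, DLG1-AS1, ACBD3-AS1, CTBP1-AS, SCUBE3-AS1, ALDH1A3-AS1, MIRLET7I and SNORD63B are uncertain. So are ribosomal proteins and pseudogenes such as RPL12P38, FCF1P2, MTCO1P53 and NMRAL2P, which share sequence with other genes.

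The first question was how many genes differed from acetone after each treatment. AM250 differed most, with 9084 of 18581 genes (4326 higher, 4758 lower). CTE1500 differed in 1043 (419 higher, 624 lower), PHE100 in 771 (363 higher, 408 lower), BAP10 in 552 (226 higher, 326 lower), BAN500 in 461 (190 higher, 271 lower) and BAP100 in 9 (8 higher, 1 lower). The order below AM250 depended on the test: DESeq2 called 1516 genes for PHE100, 1405 for CTE1500, 1073 for BAP10 and 875 for BAN500, and limma voom with library weights 3230 for BAP10, 2236 for PHE100, 822 for BAN500 and 466 for CTE1500. So did the balance of directions: edgeR with TMM called 253 higher and 190 lower genes for BAP10 and 340 and 325 for PHE100, and with the GC and length trends removed there were 542 and 281 for BAN500 and 951 and 593 for CTE1500. Changes of over 2-fold made up 3228 of the AM250 calls, 368 of the CTE1500 calls, 170 for BAN500, 147 for PHE100, 77 for BAP10 and 5 for BAP100. Of the 98 calls of gene lists by camera over all comparisons, 17 held with an estimated correlation and 81 were lost. Fry, which compares a list with no other genes, passed 60 of the 98 in the same direction: 4 of 9 for BAP100, 7 of 13 for BAN500, 1 of 5 for PHE100, 8 of 9 for CTE1500 and 10 of 10 for AM250, while the 1 list of BAP10 had adjusted p = 0.56. Genes named for the size of their change are those where all treated libraries lay on 1 side of every acetone library. By the F test of limma over all treatments, 11229 genes (60.4%) differed in at least 1 treatment.

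**Figure D1:**
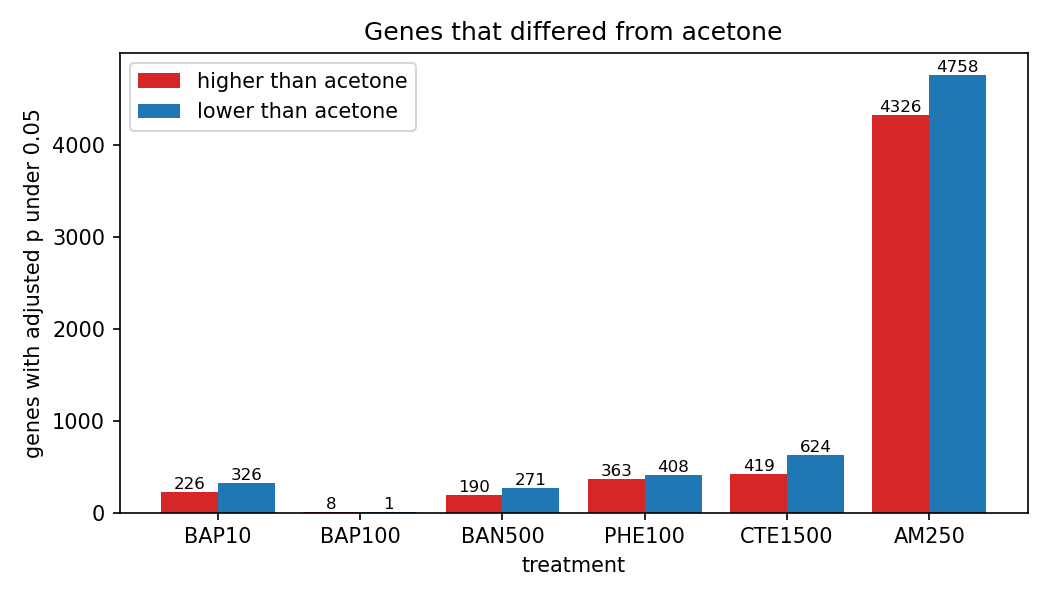
Bars show the number of genes higher (red) or lower (blue) than acetone for each treatment, by limma with an adjusted p under 0.05. AM250 had 4326 higher and 4758 lower genes, and BAP100 had 8 and 1.

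Benzo[a]pyrene at 100 µg/ml was compared with acetone to ask which genes respond to this compound. By fold, the largest called changes were in 2 targets of the aryl hydrocarbon receptor (AHR), a transcription factor that binds benzo[a]pyrene, while by camera the list of p53 targets had a smaller adjusted p than that of AHR targets. CYP1A1, which encodes an enzyme that oxidizes benzo[a]pyrene, rose 20.4-fold, from 628 ± 499 (n = 5) in acetone to 10400 ± 3010 (n = 4). CYP1B1, a related enzyme, rose 5.2-fold to 44900 ± 6380 (n = 4) from 12900 ± 12100 (n = 5). ALDH1A3, an enzyme that makes retinoic acid, rose 2.47-fold to 7080 ± 342 (n = 4), and IL19, a cytokine, rose 4.19-fold to 75.8 ± 34.8 (n = 4). EDA2R, a p53 target, rose 1.98-fold and TMEM45B 1.52-fold.

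In BAP100, 3 of 14 measured AHR targets rose and 0 fell (7 and 0 adjusted over the list alone), with a median log2 fold change of 0.84. The list was called by camera of limma with adjusted p = 9e-14, and with adjusted p = 0.00013 with an estimated correlation. Of 28 p53 targets, genes of the DNA damage response, 1 rose (16 adjusted over the list alone) and the median was 0.34, with adjusted p = 2.5e-19 by camera and adjusted p = 3.8e-05 with an estimated correlation. CDKN1A, the cell cycle inhibitor p21, was at 13100 ± 2210 (n = 4) against 7800 ± 1000 (n = 5), and MDM2, the ubiquitin ligase of p53, at 18900 ± 2530 (n = 4) against 12100 ± 1570 (n = 5), with limma adjusted p of 0.07 and 0.083 over all genes. Inflammatory cytokines had 0 members past the threshold over all genes and 11 of 23 higher adjusted over the list alone, with adjusted p = 3.4e-10 by camera and adjusted p = 0.063 with an estimated correlation. Of 14 basal markers, 0 passed over all genes and 4 were lower adjusted over the list alone, with adjusted p = 0.0014 by camera and adjusted p = 0.086 with an estimated correlation. Camera also called 5 lists of which 0 members passed over all genes. NRF2 targets (adjusted p = 0.023, and adjusted p = 0.69 with an estimated correlation), immediate early genes (adjusted p = 1e-05, and adjusted p = 0.11 with an estimated correlation) and the unfolded protein and amino acid response (adjusted p = 0.034, and adjusted p = 0.74 with an estimated correlation) were called upward. Cell cycle genes (adjusted p = 0.00036, and adjusted p = 0.72 with an estimated correlation) and ribosomal proteins (adjusted p = 0.014, and adjusted p = 0.74 with an estimated correlation) were called downward.

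The limma adjusted p-values in BAP100 were 6.9e-09 for CYP1A1, 0.005 for CYP1B1 and ALDH1A3, 0.017 for IL19, 0.041 for EDA2R and 0.0059 for TMEM45B. LINC00886 rose 1.91-fold and SLC39A11, a zinc transporter, was 1.41-fold lower. Acetone libraries differed widely in the AHR genes: CYP1A1 was 1400 and 853 in replicates 1 and 2 and between 240 and 375 in the other acetone libraries. CYP1B1 was 28300 and 23700 in the same libraries and between 3220 and 4900 in the rest. Of the 8 named genes called in BAP100, 3 (CYP1A1, CYP1B1 and ALDH1A3) kept their call whichever library was left out. CYP1B1 lost it with edgeR by either scaling, and every one of the 8 except CYP1A1 lost it in a fit to the 2 groups alone.

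**Figure D2:**
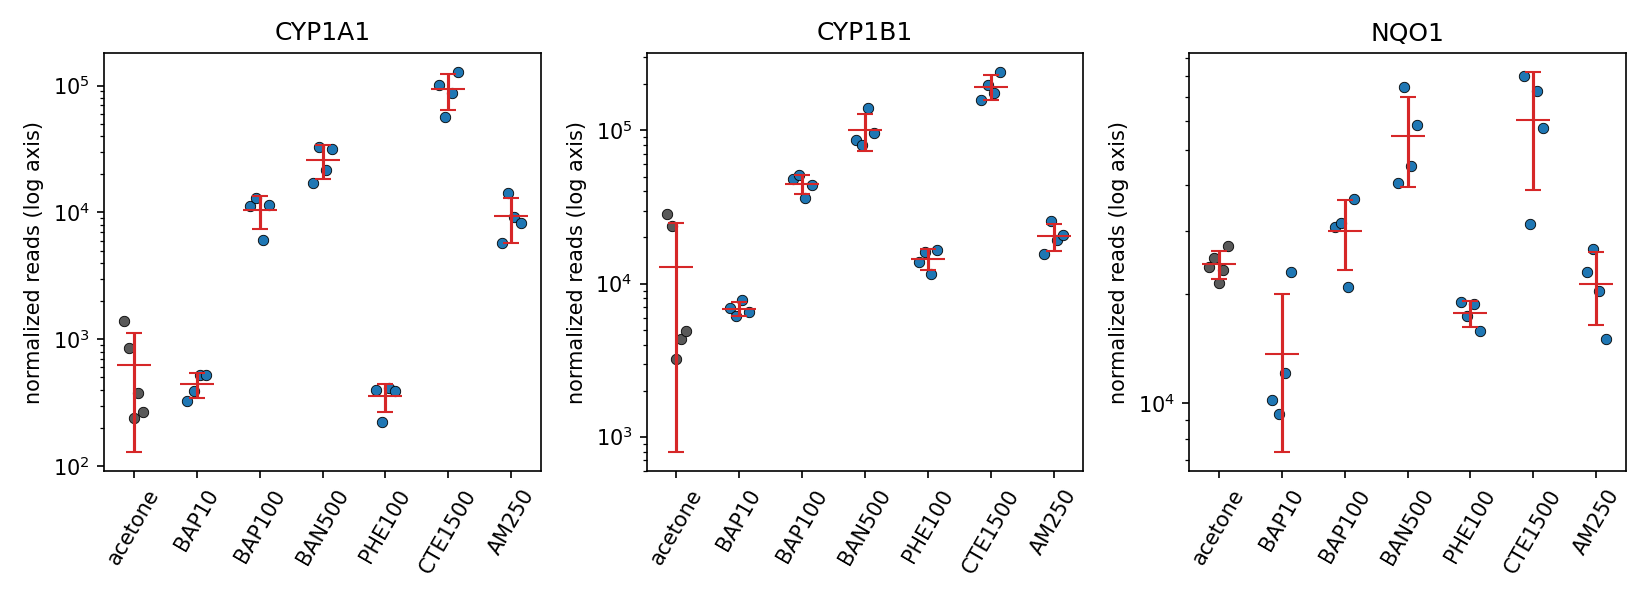
Points show normalized reads (log axis) of CYP1A1, CYP1B1 and NQO1 in each library by group, with the mean (wide line) and SD (bars). CYP1A1 averaged 628 in acetone, 10400 in BAP100, 26000 in BAN500 and 93700 in CTE1500.

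Benzo[a]pyrene at 10 µg/ml, the lower dose of the same compound, did not give an AHR response that could be detected. CYP1A1 was at 440 ± 98.3 (n = 4) against 628 ± 499 (n = 5), a log2 difference of -0.19 with a 95% interval from -0.93 to 0.55. Of 14 AHR targets, 0 rose and 1 fell, and camera gave adjusted p = 0.91. AHRR, the AHR repressor and a gene with few reads, was higher than in acetone but did not pass the limma test. The AHR target that fell was NQO1, a quinone reductase, at 13700 ± 6330 (n = 4) against 24200 ± 2160 (n = 5), 1.89-fold lower with limma adjusted p = 0.032. NQO1 was between 9370 and 12100 in 3 of the BAP10 libraries and 23000 in replicate 4.

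Of 24 mesenchymal and matrix remodelling genes, 2 rose in BAP10 and 0 fell (5 and 0 adjusted over the list alone), with adjusted p = 0.03 by camera and adjusted p = 0.87 with an estimated correlation. They were MMP14, a membrane-bound matrix protease, which rose 1.77-fold to 13400 ± 2830 (n = 4) from 7450 ± 630 (n = 5), and ITGA5, an integrin subunit, which rose 1.64-fold. Among the largest rises were those in MILIP (2.69-fold) and MYOM3 (2.4-fold). MED26 and XRCC3, a gene of recombination repair, both rose 2.16-fold, LYZ, which encodes lysozyme, 2.15-fold, PLEKHO1 2.01-fold and DUS3L 1.98-fold. The largest falls were in CERS3-AS1 (6.37-fold lower), MSH5 (3.91-fold), LINC00852 (3.63-fold), C1orf50-AS1 (2.72-fold), SNHG10 (2.36-fold), RPL12P38 (2.3-fold), C18orf21 (2.26-fold) and ZNF596 (2.12-fold). CDKN1A was at 10700 ± 927 (n = 4) with limma adjusted p = 0.095, and MDM2 at 12200 ± 799 with 0.97.

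The count of 552 for BAP10 fell to 15, 1 and 21 without BAP10 replicates 1, 2 and 3 and rose to 1843 without BAP10 replicate 4, and it was 279, 142 and 255 without acetone replicates 1, 4 and 5. A limma fit to the 2 groups alone called 0 genes (3553 at an unadjusted p under 0.05), and 0 of the 19 named genes called in BAP10 kept their call whichever library was left out.

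The doses of benzo[a]pyrene were also compared directly. At 100 against 10 µg/ml, 1112 genes differed (530 higher, 582 lower). CYP1A1 was 23.2-fold higher at the higher dose (95% interval of the log2 difference 3.76 to 5.32, limma adjusted p = 9e-09), CYP1B1 6.5-fold higher (0.0011) and IL19 4.28-fold higher (0.0061), and these 3 genes kept their call whichever library was left out. NQO1 was 2.3-fold, GDF15 1.86-fold, TIPARP 1.55-fold and MDM2 1.54-fold higher. MTCO1P53 was 9.59-fold and CERS3-AS1 5.26-fold higher, and MMP7, a matrix protease, 3.9-fold lower, as were TLN2 (2.96-fold), FMNL1 (2.59-fold), VASH1 (2.58-fold) and PRDM16 (2.54-fold). Of 14 AHR targets, 5 were higher and 0 lower (9 and 0 adjusted over the list alone), with adjusted p = 2.1e-06 by camera and adjusted p = 0.019 with an estimated correlation. Of 28 p53 targets, 9 were higher and 2 lower (12 and 2 adjusted over the list alone), with adjusted p = 0.00024 by camera and adjusted p = 0.07 with an estimated correlation. Basal markers had 3 of 14 lower and 0 higher (the same counts adjusted over the list alone), a median of -0.31, adjusted p = 0.00066 and adjusted p = 0.07 with an estimated correlation. The other called lists had adjusted p = 0.62 with an estimated correlation: cell cycle (6 of 27 lower, adjusted p = 0.00066), matrix remodelling (3 of 24 lower, adjusted p = 0.029) and inflammatory cytokines (2 of 23 higher and 1 lower, upward with adjusted p = 0.0072). The count of 1112 was 544, 105, 184 and 1791 without BAP10 replicates 1, 2, 3 and 4, and 398, 313 and 291 without BAP100 replicates 1, 2 and 3.

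Benzo[a]anthracene at 500 µg/ml was compared with acetone to ask the same of another single compound. Genes of the AHR, of the oxidative stress response and of the unfolded protein response rose together, though these lists share members (NQO1 and SLC7A11). CYP1A1 rose 50.8-fold to 26000 ± 7780 (n = 4) and CYP1B1 11.5-fold to 101000 ± 26800 (n = 4), from 628 ± 499 and 12900 ± 12100 (n = 5) in acetone. HMOX1, the haem-degrading enzyme heme oxygenase, rose 5.08-fold to 653 ± 200 (n = 4) from 124 ± 22.7 (n = 5), and SLC7A11, the cystine transporter, 3.41-fold to 20700 ± 4840 (n = 4). The interleukin genes IL1B, IL1A and IL19 rose 3.54-fold, 2.52-fold and 6.84-fold.

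In BAN500, 10 of 14 AHR targets rose and 0 fell (11 and 0 adjusted over the list alone), with adjusted p = 8.7e-21 by camera and adjusted p = 1.2e-05 with an estimated correlation. They included ALDH1A3 (3.31-fold), ALDH3A1, an aldehyde dehydrogenase (2.77-fold), TIPARP, an ADP-ribosyltransferase (2.31-fold), and AHRR, the AHR repressor (6.57-fold, 19.7 ± 11.3 against 4 ± 5.54). The call of AHRR was lost without acetone replicate 1, 3 or 5 or any BAN500 library, and with edgeR by either scaling, no filter, the 2-group fit, the replicate block or no AM250 group. Of 25 NRF2 targets, genes of the oxidative stress response, 14 rose and 0 fell (19 and 0 adjusted over the list alone), with adjusted p = 6.7e-31 by camera and adjusted p = 6.4e-05 with an estimated correlation. TXNRD1, thioredoxin reductase, rose 2.32-fold to 27500 ± 1680 (n = 4) from 11800 ± 546 (n = 5), and NQO1 rose 2.2-fold. Of 28 p53 targets, 7 rose and 0 fell (12 and 0 adjusted over the list alone), among them GDF15 (2.18-fold), EDA2R (1.85-fold), AEN (1.59-fold), CDKN1A (1.57-fold) and MDM2 (1.44-fold), with adjusted p = 5.5e-11 by camera and adjusted p = 0.00079 with an estimated correlation. Of 20 genes of the unfolded protein and amino acid response, 8 rose and 0 fell (13 and 0 adjusted over the list alone), with adjusted p = 8.7e-13 by camera and adjusted p = 0.015 with an estimated correlation. HSPA5, the chaperone BiP, rose 1.64-fold to 83900 ± 6070 (n = 4) and HYOU1, another chaperone, 1.45-fold.

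Other lists were called in BAN500 with the preset correlation alone, and few of their members passed over all genes. Immediate early genes (3 of 20 higher, 0 lower, 5 and 1 adjusted over the list alone) had adjusted p = 0.0004 by camera and adjusted p = 0.19 with an estimated correlation, and ATF3, IER3 and DUSP5 rose 2-fold, 1.85-fold and 1.58-fold. In retinoid metabolism 3 of 17 rose (3 higher and 1 lower adjusted over the list alone), with adjusted p = 0.033 by camera and adjusted p = 0.18 with an estimated correlation; DHRS9 rose 1.95-fold and the retinol receptor gene STRA6 1.63-fold. Inflammatory cytokines had 3 of 23 higher and 1 lower (3 and 2 adjusted over the list alone), with adjusted p = 0.045 and adjusted p = 0.55 with an estimated correlation. Of 22 squamous markers 1, KRT6B, rose 2.01-fold (2 adjusted over the list alone), with adjusted p = 0.0035 and adjusted p = 0.19 with an estimated correlation. Among basal markers 3 of 14 fell (4 adjusted over the list alone), KRT5, BCAM and NGFR, by camera adjusted p = 0.024 and adjusted p = 0.19 with an estimated correlation. KRT5, a keratin of basal cells, was at 20000 ± 2940 (n = 4) against 30500 ± 4580 (n = 5). Among ciliated markers 2 of 19 fell (13 adjusted over the list alone), SPAG6 (1.85-fold lower) and FOXJ1, a transcription factor of motile cilia (1.96-fold lower), with adjusted p = 2.1e-10 and adjusted p = 0.19 with an estimated correlation. Cell cycle genes (2 of 27 lower, CDC20 and CENPF, 2 adjusted over the list alone) had adjusted p = 1.8e-05 and adjusted p = 0.35 with an estimated correlation. Interferon response genes (2 of 24 lower, OAS3 and MX1, 11 adjusted over the list alone) had adjusted p = 1.9e-07 and adjusted p = 0.25 with an estimated correlation.

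Of 24 mesenchymal and matrix remodelling genes, 5 fell in BAN500 (7 adjusted over the list alone), with adjusted p = 0.0068 by camera and adjusted p = 0.42 with an estimated correlation. TNC, the matrix protein tenascin C, was at 2920 ± 614 (n = 4) against 5120 ± 645 (n = 5), LOX, lysyl oxidase, 1.94-fold lower and MMP13 3.21-fold lower. The largest falls were in MACROD2 (10.3-fold lower), ADGRL3 (8.83-fold), SDK1 (5.3-fold), SOBP (3.93-fold), APOB (3.79-fold), CYP2F1 (3.74-fold), EDIL3 (3.6-fold) and MMP7 (3.54-fold). EPGN, an EGF receptor ligand, rose 4.46-fold, PLA2G4E, a phospholipase, 4.45-fold, NMRAL2P 4.31-fold and the imprinted RNA H19 4.02-fold. Limma adjusted p-values ranged down to 6e-12 (CYP1A1) and 4.6e-09 (TXNRD1), and 29 of the 51 named genes called kept their call whichever library was left out. The rest, which lost it without 1 library or more, were AHRR, ALDH3A1, GDF15, EDA2R, CDKN1A, MDM2, IER3, DUSP5, STRA6, IL1RN, KRT6B, KRT5, NGFR, SPAG6, FOXJ1, CDC20, CENPF, OAS3, MX1, PLA2G4E, CYP2F1 and SOBP. The count of 461 was 245 and 293 without acetone replicates 3 and 4, and 268 and 299 without BAN500 replicates 2 and 4.

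Phenanthrene at 100 µg/ml, a compound with fewer fused rings than benzo[a]pyrene, was compared with acetone. AHR genes did not pass the test: CYP1A1 was at 357 ± 88.9 (n = 4) against 628 ± 499 (n = 5), a log2 difference of -0.5 with a 95% interval from -1.24 to 0.24, and 0 of 14 AHR targets passed over all genes or adjusted over the list alone. CYP1B1 was at 14600 ± 2280 (n = 4), with limma adjusted p = 0.24. Single genes of motile cilia and of secretory cells were higher, but the list calls of ciliated and of club and secretory markers were lost with an estimated correlation (adjusted p = 0.62 and 0.51) and did not pass fry (adjusted p = 0.18 and 0.054). DYNLRB2, a dynein light chain, rose 2.79-fold to 1200 ± 311 (n = 4) from 443 ± 182 (n = 5), DYDC1 3.02-fold, CFAP300, a ciliary protein, 2.64-fold and RSPH4A, of the radial spoke, 1.79-fold. BPIFB1, a secreted antimicrobial protein, rose 1.64-fold to 174000 ± 13200 (n = 4) from 107000 ± 10200 (n = 5).

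Of 19 ciliated markers, 1 rose in PHE100 over all genes and 12 adjusted over the list alone, with a median log2 fold change of 0.58 and adjusted p = 3.8e-06 by camera, and adjusted p = 0.62 with an estimated correlation. Of 13 club and secretory markers, 2 rose (8 adjusted over the list alone), BPIFB1 and PIGR, the receptor that carries antibodies across epithelia (1.52-fold), with adjusted p = 8.6e-06 by camera and adjusted p = 0.51 with an estimated correlation. Of 14 basal markers, 1 fell (2 adjusted over the list alone), KRT14, a keratin, at 20700 ± 3310 (n = 4) against 35500 ± 8100 (n = 5), with adjusted p = 0.016 by camera and adjusted p = 0.51 with an estimated correlation. Cholesterol synthesis genes fell in 5 of 20 (6 adjusted over the list alone), with adjusted p = 2.5e-05 by camera and adjusted p = 0.51 with an estimated correlation. They included MVD, of the mevalonate pathway, at 497 ± 67.7 (n = 4) against 1020 ± 227 (n = 5), LSS (1.69-fold lower) and MVK (1.55-fold lower). Of 27 cell cycle genes, 4 fell (13 adjusted over the list alone), among them MCM2, of the replicative helicase (2.04-fold lower), E2F1 (1.5-fold) and CCNB1, cyclin B1 (1.46-fold), with adjusted p = 1.5e-06 by camera and adjusted p = 0.51 with an estimated correlation.

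The other largest rises in PHE100 were in GPA33 (3.58-fold), ACBD3-AS1 (3.1-fold), HBB (2.74-fold), which encodes beta globin, DLG1-AS1 (2.71-fold) and FCF1P2 (2.62-fold). The largest falls were in DDX49 (5.64-fold lower), SRRM5 (4.35-fold), CTBP1-AS (3.8-fold), GPX1, a glutathione peroxidase (3.8-fold), SNORD63B (3.38-fold), SNHG3 (3.33-fold), IRX1 (3.22-fold) and LRRC75B (3.21-fold). GPX1 ranged from 3640 to 22400 and DDX49 from 840 to 5410 over the acetone libraries. Named genes called in PHE100 had limma adjusted p-values from 0.015 (DYDC1) to 0.049 (GPX1) or 0.0496 (SNORD63B), and 0 of these 26 kept their call whichever library was left out. The count of 771 by limma was 0 without acetone replicate 4 (3520 at an unadjusted p under 0.05) and 0 without PHE100 replicate 1 (3454 at an unadjusted p under 0.05), while DESeq2 and edgeR with TMM called 1516 and 665 genes over all libraries. It was 359 without acetone replicate 1, and 351, 320 and 246 without PHE100 replicates 2, 3 and 4.

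Benzo[a]pyrene and phenanthrene were compared at the same mass dose of 100 µg/ml. They differed in 79 genes (39 higher and 40 lower in BAP100). CYP1A1 was 28.9-fold higher after benzo[a]pyrene (log2 difference 4.85 ± 0.38 SE, 95% interval 4.07 to 5.63, limma adjusted p = 1.6e-09), IL1B 4.08-fold (1.38 to 2.67, 0.0025), CDKN1A 1.74-fold (0.46 to 1.14, 0.03) and TIPARP 1.6-fold (0.35 to 1, 0.048). ALDH1A3-AS1 was 3.54-fold, MRGPRX3 3-fold and CORO1A 2.92-fold higher, and TMEM132B 3.59-fold, GMNC, a regulator of multiciliated cells, 3.13-fold, MXRA5 2.79-fold, GAS1 2.77-fold and EDIL3 2.38-fold lower. CYP1B1 did not pass (log2 difference 1.63, interval 0.79 to 2.46, adjusted p = 0.065), nor did MDM2 (0.2, interval -0.1 to 0.51) or HMOX1 (-0.26, interval -0.79 to 0.28), and these intervals do not show that the 2 compounds act alike. Of 14 AHR targets, 3 were higher after benzo[a]pyrene and 0 lower (9 and 0 adjusted over the list alone), with adjusted p = 1.6e-09 by camera and adjusted p = 0.0023 with an estimated correlation. Of 28 p53 targets, 3 were higher and 0 lower (12 and 0 adjusted over the list alone), with adjusted p = 1.7e-07 and adjusted p = 0.0095 with an estimated correlation. Ciliated (median -0.53) and club and secretory markers (median -0.56) were lower after benzo[a]pyrene by camera (adjusted p = 7.6e-08 and 6.8e-06), with adjusted p = 0.32 and 0.2 with an estimated correlation, and 0 members of either passed over all genes (2 and 3 lower adjusted over the list alone). Ionocyte markers were also called downward (adjusted p = 0.036, and adjusted p = 0.2 with an estimated correlation). Lists called upward and lost with an estimated correlation (adjusted p in brackets) were NRF2 targets (0.0067, 0.38), cell cycle (0.0067, 0.75), inflammatory cytokines (1.2e-05, 0.2), cholesterol synthesis (1.4e-06, 0.2), immediate early genes (0.00011, 0.2) and squamous markers (0.036, 0.38). CYP1A1 and IL1B kept their call whichever library was left out. The count of 79 was 4, 9 and 4 without BAP100 replicates 1, 2 and 4, and 3, 42, 3 and 179 without PHE100 replicates 1, 2, 3 and 4.

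Benzo[a]anthracene was compared with benzo[a]pyrene and phenanthrene, at doses that differ (500 against 100 µg/ml). Against BAP100, 15 genes differed (13 higher, 2 lower). HMOX1 was 3.65-fold (95% interval of the log2 difference 1.34 to 2.4), SLC7A11 2.39-fold, ABCC3, an organic anion transporter, 2.38-fold and TRIM16L 2.01-fold higher in BAN500, each with limma adjusted p = 0.00022, and NMRAL2P was 2.62-fold higher (0.0038). These 5 genes kept their call whichever library was left out. VEPH1 was 4.81-fold and SERPINB10 3.29-fold lower. NRF2 targets had 7 of 25 higher and 0 lower (23 and 0 adjusted over the list alone), with adjusted p = 1.9e-44 by camera and adjusted p = 8.3e-06 with an estimated correlation. AHR targets had 0 of 14 past the threshold over all genes and 5 higher adjusted over the list alone, with adjusted p = 8.1e-10 by camera and adjusted p = 0.0015 with an estimated correlation, and CYP1A1 had a log2 difference of 1.32 (interval 0.54 to 2.1, limma adjusted p = 0.24). The unfolded protein and amino acid response had 1 of 20 higher (7 adjusted over the list alone), with adjusted p = 2.8e-14 and adjusted p = 0.012 with an estimated correlation. The 9 other called lists had 0 members past the threshold over all genes and were lost with an estimated correlation (both adjusted p in brackets). Downward they were ciliated markers (1e-16, 0.12; median -0.63, 10 of 19 lower adjusted over the list alone), interferon response (2.5e-12, 0.13; 9 of 24 lower over the list alone), matrix remodelling (2.1e-05, 0.19), inflammatory cytokines (0.0007, 0.29) and club and secretory markers (0.0015, 0.35). Upward they were squamous markers (0.00046, 0.13), cholesterol synthesis (0.01, 0.46), heat shock (0.02, 0.19) and ribosomal proteins (0.042, 0.63). Without BAN500 replicate 1 the count of 15 rose to 29 (12 higher, 17 lower), and the excess of higher genes was also absent by DESeq2 (31 and 31) and by voom with library weights (78 and 88).

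Against PHE100, BAN500 differed in 2204 genes (816 higher, 1388 lower), again at doses that differ. With the GC and length trends removed the balance turned, with 1526 higher and 1274 lower. CYP1A1 was 72-fold, CYP1B1 6.82-fold, IL1B 5.94-fold, NMRAL2P 5.3-fold, HMOX1 3.06-fold, NQO1 3-fold, GDF15 2.63-fold, TIPARP 2.49-fold and CDKN1A 1.64-fold higher, and RLBP1, a retinoid-binding protein, 11.5-fold higher. ADGRL3 was 12.9-fold, MACROD2 12.8-fold, NCBP2L 9.71-fold, CHSY3 8.1-fold and NEGR1 7.99-fold lower. These 15 genes kept their limma call whichever library was left out, with adjusted p-values from 2.5e-12 (CYP1A1) to 0.0096 (CHSY3). Of 14 AHR targets 10 were higher and 0 lower (11 and 0 adjusted over the list alone), with adjusted p = 1.4e-13 by camera and adjusted p = 0.00031 with an estimated correlation, and of 25 NRF2 targets 21 were higher and 0 lower (23 and 0 adjusted over the list alone), with adjusted p = 2.2e-22 and adjusted p = 0.00055 with an estimated correlation. Of 19 ciliated markers 17 were lower in BAN500 (19 adjusted over the list alone), with a median log2 difference of -1.23, adjusted p = 1.9e-17 by camera and adjusted p = 0.1 with an estimated correlation. Of 22 squamous markers 6 were higher (7 adjusted over the list alone), with adjusted p = 0.00023 and adjusted p = 0.11 with an estimated correlation. Other calls that an estimated correlation did not keep (both adjusted p in brackets) were downward for club and secretory markers (7 of 13 lower, 2.7e-07, 0.12), ionocyte markers (1 of 5 lower, 0.032, 0.12) and interferon response (7 of 24 lower, 1e-05, 0.35). They were upward for p53 targets (9 of 28 higher and 1 lower, 0.00035, 0.1), cholesterol synthesis (7 of 20 higher, 2.9e-07, 0.12), unfolded protein and amino acid response (3 of 20 higher, 8.5e-06, 0.12) and immediate early genes (5 of 20 higher, 0.0038, 0.3). The count of 2204 was 1167 without BAN500 replicate 2 and 1420 without PHE100 replicate 1.

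Coal tar extract at 1500 µg/ml, a complex mixture, was compared with acetone. It gave the largest AHR response of the 6 treatments by the fold of CYP1A1. CYP1A1 (ENSG00000140465, GRCh38 chromosome 15, 74719542 to 74725610) rose 182-fold to 93700 ± 29800 (n = 4) from 628 ± 499 (n = 5). CYP1B1 (ENSG00000138061, chromosome 2, 38066973 to 38109902) rose 22.4-fold to 194000 ± 35700 (n = 4) from 12900 ± 12100 (n = 5). AHRR (ENSG00000063438, chromosome 5, 304176 to 438291) rose 43.9-fold to 129 ± 43.7 (n = 4) from 4 ± 5.54 (n = 5), ALDH3A1 5.09-fold and TIPARP 3.34-fold.

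In CTE1500, 11 of 14 AHR targets rose and 0 fell (13 and 0 adjusted over the list alone), with adjusted p = 2e-23 by camera and adjusted p = 4.1e-06 with an estimated correlation. Of 25 NRF2 targets, 15 rose and 0 fell (18 and 0 adjusted over the list alone), with adjusted p = 3e-20 by camera and adjusted p = 0.0011 with an estimated correlation. SLC7A11 rose 2.92-fold, NQO1 2.36-fold to 60500 ± 21700 (n = 4), TXNRD1 2.2-fold, ME1, malic enzyme, 2.05-fold and HMOX1 1.82-fold. Of 28 p53 targets, 7 rose and 0 fell (9 and 0 adjusted over the list alone), with adjusted p = 9.3e-08 by camera and adjusted p = 0.0065 with an estimated correlation. RRM2B, a ribonucleotide reductase subunit, and MDM2 both rose 1.78-fold, and ZMAT3 and CDKN1A 1.62-fold. IL19 rose 7.23-fold, C5AR2, a receptor of complement fragments, 6.95-fold, H19 6.94-fold, PLA2G4E 6.43-fold and COMP, a matrix protein, 8.99-fold.

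Cell cycle genes fell in 12 of 27 in CTE1500 and rose in 0 (17 and 0 adjusted over the list alone), with adjusted p = 2.7e-11 by camera and adjusted p = 0.2 with an estimated correlation. MKI67, the proliferation marker, was at 1060 ± 348 (n = 4) against 1940 ± 237 (n = 5), CDC20 2.02-fold and UBE2C 1.92-fold lower. Interferon response genes fell in 7 of 24 (12 adjusted over the list alone), with adjusted p = 3.4e-09 and adjusted p = 0.22 with an estimated correlation, among them RSAD2 (2.57-fold lower), IFIT2 (2.16-fold) and OAS3 (1.6-fold). Matrix remodelling genes fell in 8 of 24 and rose in 0 (8 and 1 adjusted over the list alone), with adjusted p = 0.00036 and adjusted p = 0.32 with an estimated correlation, among them MMP13 (3.34-fold lower), TNC (2.84-fold) and LOX (1.88-fold). Ciliated markers fell in 5 of 19 (13 adjusted over the list alone), with adjusted p = 6.7e-08 and adjusted p = 0.32 with an estimated correlation, among them TEKT2 (2.21-fold lower), FOXJ1 (1.94-fold) and SPAG6 (1.81-fold). Basal markers fell in 3 of 14 (4 adjusted over the list alone), NGFR (3.5-fold lower), BCAM (1.63-fold) and KRT5 (1.52-fold), with adjusted p = 0.0042 and adjusted p = 0.16 with an estimated correlation. Ribosomal proteins had 0 of 26 past the threshold over all genes or over the list alone, a median of -0.2, adjusted p = 0.016 by camera and adjusted p = 0.7 with an estimated correlation.

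The largest falls in CTE1500 were in ANKRD1 (9.51-fold lower), MACROD2 (9.38-fold), ADGRL3 (7.12-fold), NEURL3 (6.08-fold), KCNJ5 (5.81-fold), SPOCK3 (5.35-fold), PTPRR (5.19-fold) and SDK1 (5.07-fold). Limma adjusted p-values were 2.1e-15 for CYP1A1, 2.4e-09 for CYP1B1, 1e-05 for AHRR and 5.8e-07 for ANKRD1, and 37 of the 42 named genes called kept their call whichever library was left out, the others being HMOX1, BCAM, SPAG6, FOXJ1 and TEKT2. The count of 1043 was 1957, 621 and 600 without CTE1500 replicates 1, 2 and 4, and 671 and 652 without acetone replicates 3 and 4.

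The simulated air mixture at 250 µg/ml was compared with acetone. Most measured genes of ciliated, secretory and goblet cells were higher and many of matrix remodelling and inflammation lower, but with an estimated correlation camera kept 0 of the 10 list calls, while fry passed 10. MUC5AC (ENSG00000215182, GRCh38 chromosome 11, 1157953 to 1201138), the gel-forming mucin of goblet cells, rose 17.1-fold to 49600 ± 18500 (n = 4) from 2780 ± 673 (n = 5), and MUC5B, another airway mucin, 6.34-fold to 21200 ± 7350 (n = 4). TPPP3, of ciliated cells, rose 5.55-fold to 7100 ± 1380 (n = 4). MMP9 (ENSG00000100985, chromosome 20, 46008908 to 46016561), a gelatinase, was 9.06-fold lower at 509 ± 270 (n = 4) against 4170 ± 865 (n = 5), and DSC3, a desmosomal cadherin, 3.03-fold lower. CYP1A1 rose 18-fold to 9340 ± 3580 (n = 4).

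Of 19 ciliated markers, 18 rose in AM250 (18 adjusted over the list alone), among them CCDC78 (4.22-fold) and DNAI1, of the dynein arm (3.52-fold), with adjusted p = 3.1e-09 by camera and adjusted p = 0.31 with an estimated correlation. Of 13 club and secretory markers, 12 rose (13 adjusted over the list alone), among them MSMB (3.77-fold), WFDC2 (3.67-fold) and BPIFB1 (2.21-fold), with adjusted p = 3.4e-06 and adjusted p = 0.29 with an estimated correlation. Of 13 goblet markers, 9 rose and 1 fell (the same counts adjusted over the list alone), including SPDEF, a goblet cell transcription factor (2.51-fold), with adjusted p = 0.00027 and adjusted p = 0.29 with an estimated correlation. Basal markers went both ways, 3 of 14 higher and 6 lower (3 and 6 adjusted over the list alone), with camera adjusted p = 0.18. Ribosomal proteins rose in 19 of 26 and fell in 1 (20 and 1 adjusted over the list alone), RPL19 by 3.48-fold, RPL32 by 2.35-fold and RPL18 by 2.16-fold, with adjusted p = 1.3e-07 and adjusted p = 0.29 with an estimated correlation. Beside these groups, the share of normalized reads in ribosomal protein genes of the list was 0.948% ± 0.189 (n = 4) in AM250 against 0.516% ± 0.0482 (n = 5) in acetone, and that in nuclear pseudogenes of mitochondrial genes 1.93% ± 0.539 against 0.982% ± 0.35. Across genes, which are not independent replicates, log2 fold changes of AM250 correlated with GC content at 0.4 and with log gene length at -0.21.

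In AM250 the AHR targets went both ways, 5 of 14 higher and 4 lower (5 and 4 adjusted over the list alone), with a median of -0.09, a mean of 0.44 and an upward test with camera adjusted p = 0.73. ALDH3A1 rose 7.39-fold, AHRR 4.76-fold and CYP1B1 2.35-fold, while TIPARP was at 4100 ± 935 (n = 4) against 4820 ± 1080 (n = 5) with limma adjusted p = 0.2. NRF2 targets had 11 of 25 higher and 5 lower (11 and 5 adjusted over the list alone) with camera adjusted p = 0.33, and HMOX1 rose 2.09-fold. Of 28 p53 targets 10 were higher and 11 lower (10 and 12 adjusted over the list alone), with a median of -0.2, a mean of 0.02 and a downward test with camera adjusted p = 0.89, while CDKN1A rose 1.69-fold and GDF15 1.64-fold.

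Mesenchymal and matrix remodelling genes fell in 20 of 24 in AM250 and rose in 0 (21 and 0 adjusted over the list alone), with a median log2 fold change of -1.55, adjusted p = 3.1e-09 by camera and adjusted p = 0.29 with an estimated correlation. ITGB6, an integrin subunit, was 3.79-fold and TNC 3.5-fold lower. Genes of cell junctions fell in 15 of 26 and rose in 8 (15 and 8 adjusted over the list alone), with adjusted p = 0.046 and adjusted p = 0.29 with an estimated correlation. CLDN1, claudin 1, was at 7140 ± 601 (n = 4) against 27600 ± 2860 (n = 5), and DSG3 2.35-fold lower. The unfolded protein and amino acid response fell in 12 of 20 and rose in 3 (13 and 3 adjusted over the list alone), with adjusted p = 0.00039 and adjusted p = 0.31 with an estimated correlation: PSAT1, of serine synthesis, was 3.89-fold, SEL1L 2.75-fold and DNAJC3 2.12-fold lower. Inflammatory cytokines fell in 12 of 23 and rose in 3 (13 and 3 adjusted over the list alone), with adjusted p = 0.047 and adjusted p = 0.78 with an estimated correlation: CXCL5, a chemokine, was 3.95-fold, PTGS2, cyclooxygenase 2, 2.83-fold and ICAM1 2.25-fold lower. Interferon response genes fell in 12 of 24 and rose in 1 (13 and 1 adjusted over the list alone), with adjusted p = 0.021 and adjusted p = 0.86 with an estimated correlation: CXCL10 was 9.67-fold, RSAD2 3.07-fold and RIGI, an RNA sensor, 1.92-fold lower.

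Beside CYP1A1 and MUC5AC, the largest rises in AM250 were in MUC2, an intestinal mucin (18.1-fold), H19 (11.3-fold), SCUBE3-AS1 (9.31-fold), FOXI1, the transcription factor of ionocytes (9.24-fold), KLK12 (9.05-fold) and DPEP2 (8.89-fold). The largest falls were in IL1R2, the decoy receptor of interleukin 1 (20.6-fold lower), LINC01705 (18.4-fold), ITGB3 (15-fold), HEPHL1 (14-fold), TNFRSF9 (13-fold), MMP10 (12.5-fold), GPC6 (11.5-fold) and NTM (11.1-fold). Limma adjusted p-values were 1.4e-11 for MUC5AC, 5.7e-09 for MUC5B, 1.2e-09 for MMP9 and 5.2e-12 for DSC3, and 50 of the 51 named genes called kept their call whichever library was left out, the exception being GDF15 without AM250 replicate 1. AHRR and CYP1B1 lost their call with DESeq2 and with edgeR by either scaling. With the trends on GC content and length removed, the calls of HMOX1 and CDKN1A were lost, GDF15 was at -0.08 on the log2 scale and MDM2 rose by 0.38.

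Some lists were called for 0 of the 6 treatments against acetone by camera, at either correlation. The smallest adjusted p was 0.14 (PHE100) for DNA repair and damage signalling (28 genes measured), 0.16 (BAN500) for heat shock (14), 0.11 (PHE100) for ionocyte markers (5), 0.19 (BAN500) for neuroendocrine markers (3), 0.44 (BAP10) for fibroblast markers (4), 0.33 (BAP10 and CTE1500) for endothelial markers (6) and 0.58 (BAP10) for leukocyte markers (3).

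The 2 mixtures were compared with each other at doses that differ (1500 against 250 µg/ml). They differed in 9730 genes (4869 higher and 4861 lower in CTE1500). CYP1A1 was 10.1-fold, CYP1B1 9.52-fold, AHRR 9.23-fold, TIPARP 3.94-fold, NQO1 2.73-fold and MDM2 1.99-fold higher in CTE1500, as were IL1R2 (33.2-fold), MMP1 (24.4-fold), HEPHL1 (18.8-fold), MMP10 (17-fold) and MIRLET7I (16.4-fold). FABP6 was 26.5-fold, FKBP6 18.5-fold, MUC12 17.5-fold, TMEM190 17.4-fold and MYBPC1 17-fold lower. These 16 genes kept their limma call whichever library was left out, with adjusted p = 1.9e-08 for CYP1A1. HMOX1 (log2 difference -0.2, 95% interval -0.73 to 0.34) and CDKN1A (-0.06, interval -0.4 to 0.28) did not pass, and with the GC and length trends removed CDKN1A was higher in CTE1500 by 0.59. Of 14 AHR targets 11 were higher and 0 lower (12 and 1 adjusted over the list alone), with adjusted p = 5.2e-05 by camera and adjusted p = 0.083 with an estimated correlation. Of 19 ciliated markers 19 were lower (19 adjusted over the list alone), with adjusted p = 1.6e-11 and adjusted p = 0.32 with an estimated correlation. Also lower in CTE1500, each with adjusted p = 0.32 with an estimated correlation, were ribosomal proteins (21 of 26 lower and 1 higher, median -1.05, adjusted p = 6.1e-08), club and secretory markers (12 of 13 lower, adjusted p = 6.2e-05) and goblet markers (8 of 13 lower and 1 higher, adjusted p = 0.0022). The share of normalized reads in ribosomal protein genes was 0.413% ± 0.0603 (n = 4) in CTE1500 against 0.948% ± 0.189 (n = 4) in AM250, and that in nuclear pseudogenes of mitochondrial genes 0.992% ± 0.0888 against 1.93% ± 0.539. Further calls that an estimated correlation did not keep (both adjusted p in brackets) were upward for matrix remodelling (13 of 24 higher, 0.00014, 0.32), unfolded protein and amino acid response (13 of 20 higher and 3 lower, 0.00047, 0.32), NRF2 targets (11 of 25 higher and 2 lower, 0.03, 0.5) and p53 targets (15 of 28 higher and 7 lower, 0.047, 0.34). Cell cycle genes were called downward (11 of 27 lower and 1 higher, 0.035, 0.67).

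The last question was whether treatments changed the same genes. BAN500 and CTE1500 had the highest correlation of log2 fold changes across genes, Pearson's r of 0.66 and Spearman's rho of 0.65, with a covariance of 0.183. Unchanged groups that shared 1 simulated acetone group, with each gene drawn independently, gave 0.44, 0.4 and 0.0697. With the real acetone libraries split so that none was shared, r averaged 0.34 (split r, from 0.28 to 0.39 over the splits). These 2 treatments shared 121 higher and 193 lower genes, with 0 in opposite directions, where independent lists of the same sizes would share 4.28 and 9.1. BAP100 had r of 0.57 and rho of 0.57 with BAN500 (covariance 0.117, split r 0.18, from 0.07 to 0.26). With CTE1500 it had r of 0.52 and rho of 0.52 (covariance 0.119, split r 0.18, from 0.1 to 0.25). With PHE100 it had r of 0.45 and rho of 0.45 (covariance 0.0964, split r 0.11, from 0.05 to 0.19). With both BAN500 and CTE1500, BAP100 shared 8 higher and 1 lower gene, that is, all 9 of its calls, where independent lists would share 0.0818 and 0.0146, and 0.18 and 0.0336. BAP10 had r of 0.34 and rho of 0.39 with AM250 (covariance 0.147, split r 0.16, from 0 to 0.3). The pair had 170 shared higher and 258 shared lower genes and 12 in opposite directions, where independent lists would share 52.6 and 83.5. That pair and the other 10 of the 15 had r below the simulated 0.44. The covariance was nevertheless above the simulated 0.0697 for BAP10 and AM250, for PHE100 and AM250 (0.1), for PHE100 and CTE1500 (0.0846) and for BAP10 and PHE100 (0.0841), so r below 0.44 does not mean less agreement than between unchanged groups. Genes are not independent replicates, and neither the simulated nor the independent value stands for a shared effect. The independent values also ignore that all comparisons use the same acetone libraries, which can itself raise the number of shared genes.

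**Figure D3:**
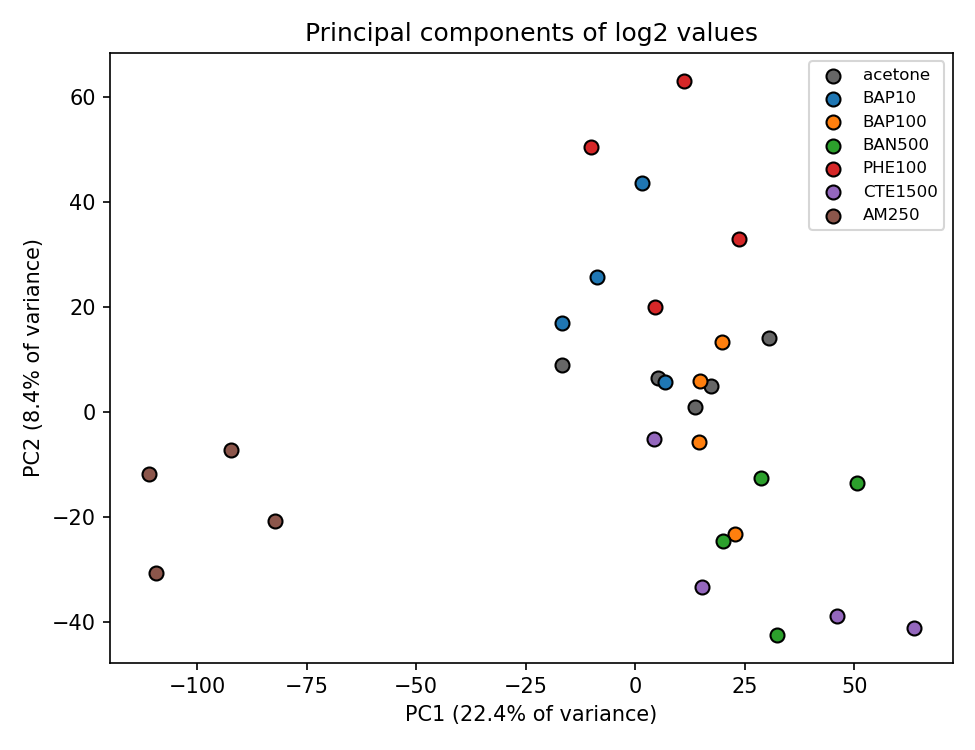
Points show the 29 libraries on the first (x axis, 22.4% of variance) and second (y axis, 8.4%) principal components of log2 values, coloured by group. The 4 AM250 libraries lie at the left, apart from the other 25.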

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

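The tests of the patterns below, removal of the GC and length trends among them, were chosen after the results had been seen, while omission of single libraries and the estimated correlation were planned.

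A library was singled out when its gap to the nearest other library of its group, divided by the whole range of the group, passed Dixon's 95% critical value. Of 451 tests of a named gene in a group, 23 passed, where chance gives 22.6, and of 35 tests of library measures 1 passed, where chance gives 1.75. In acetone, CXCL10 was 260 in replicate 3 (others 66.6 to 73.7 at the nearest), TNFRSF9 93.4 in replicate 2, LINC01705 8.89 in replicate 5, and CCNB1 4080 and SRRM5 63.8 in replicate 4. The share of reads in the 10 highest genes was 5% in acetone replicate 3 and between 4.02% and 4.22% in the other acetone libraries. Replicate 3 also stood apart by chi-square per degree of freedom (62.8 to 111 against the other acetone libraries, 22.2 to 55.6 among them) and had the highest acetone share of reads in nuclear pseudogenes of mitochondrial genes (1.51%, others 0.633% to 1.14%). In BAP10, CDKN1A was 12100 in replicate 2 (others 10100 to 10400) and ALDH3A1 6690 in replicate 1 (others 4020 to 4340). In BAP100, IL19 was 128 in replicate 3 (others 54.7 to 62).

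In PHE100, CYP1A1 was 224 in replicate 2 (others 394 to 413), MCM2 999 and NEGR1 22.7 in replicate 1, and DLG1-AS1 63.5 and GMNC 199 in replicate 4. In CTE1500, SPOCK3 was 15.3 in replicate 2, and ANKRD1 21.4 and HEPHL1 145 in replicate 4 (HEPHL1 in the others 658 to 770). In AM250, TIPARP was 2710 (others 4370 to 4710) and SEL1L 3200 in replicate 1, RPL19 5930 (others 12400 to 13700) and DSC3 4940 in replicate 2, and RIGI 1530, TNC 1580 and MMP1 355 in replicate 4 (MMP1 in the others 96.4 to 101). The number of such values is what chance gives, and no explanation was tested for any of them.

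More genes were called for BAP10 (552) than for BAP100 (9), although CYP1A1 rose only at the higher dose. AHR activation at the lower dose was not decided by CYP1A1. Its upper 95% bound of the log2 fold change in BAP10 was 0.55, but the acetone libraries differed widely in this gene. High values in some acetone libraries lower that bound, and AHRR, another AHR target, was higher in BAP10 without passing the test. Whether a single library was the source of the larger count could not be decided. Omission of any of 3 BAP10 libraries took it below the full count divided by 1.5, but a smaller group can lower the count whatever the cause. Omission of acetone replicate 1, 4 or 5 did so too (279, 142 and 255). The remaining BAP10 library, replicate 4, stood apart (chi-square per degree of freedom 63.8 to 88 against the others, 16.6 to 27 among them), and the count rose to 1843 without it. A trend on GC content and gene length stays open: with it removed 206 genes were called for BAP10 and 16 for BAP100 (5 and 12 with the replicate block as well), but the BAP10 count then ranged from 1 to 1829 with 1 library left out. No biological explanation was excluded or shown.

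AM250 differed from acetone in 48.9% of the tested genes. Every library had been put on 1 scale before the fit. The median absolute log2 fold change of the called genes, 0.81, therefore could not test separate normalization of the AM250 libraries. The values as deposited gave 9076 called genes against 9084 on 1 scale, and the scales differed by at most 0.027, which argues against it as the cause. GC content and length trends as the whole cause were argued against. With the trends removed 7033 genes were called (6130 to 7156 with 1 library left out), of which 5493 were among the 9084. With the replicate block as well, 5021 of 6278 were. The rest of the 9084 lost their call, so the trends as a part of the cause stay open. The labels name no library or sequencing batch, so none was tested: 0 libraries of other groups were deposited with factors of the scaling over all libraries, but a scaling is not a batch. An effect of the mixture stays open.

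In PHE100 the lists of ciliated and of club and secretory markers were called upward and that of basal markers downward with the preset correlation. These calls were lost with an estimated one (adjusted p = 0.62, 0.51 and 0.51; by fry 0.18, 0.054 and 0.045), and 1 of 19, 2 of 13 and 1 of 14 markers passed over all genes. Whether a lower share of basal cells was the whole cause, which would raise the markers of every other cell type alike, could not be decided. The median log2 fold change of squamous markers was -0.3 ± 0.14 SE over the members (-0.37 to -0.21 with 1 library left out), against 0.58 ± 0.06 (ciliated), 0.64 ± 0.06 (club and secretory), 0.72 ± 0.29 (ionocyte) and 0.16 ± 0.15 (goblet). Those SEs treat the genes of a list as replicates and are those of a mean. Between libraries the mean of the squamous markers was -0.22 ± 0.19 SE, and camera gave that list adjusted p = 0.14. A fall of squamous markers was therefore not shown. The lists with few members were at -0.16 ± 0.24 (neuroendocrine), 0 ± 0.42 (fibroblast), 0.11 ± 0.43 (endothelial) and 0.48 ± 0.83 (leukocyte). With GC content and length trends removed, the ciliated and the club and secretory lists were called by camera with adjusted p = 3.2e-07 each and the basal list was not, with adjusted p = 0.12, so that trend stays open for the basal markers. An effect of phenanthrene on differentiation was not tested.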

How the results depend on the processing

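The settings edgeR with TMM, other pseudocounts, values as deposited, TMM factors, omission of the AM250 group and removal of the GC and length trends were chosen after seeing the data. The cause was not tested for any change given here, except where fewer genes or libraries entered by construction. Counts of genes within 1.5 times the main count under every setting other than omission of 1 library were those of AM250 and of CTE1500 against AM250, and that of any treatment. A similar count need not hold the same genes. For AM250 with the GC and length trends removed, 5493 of the 7033 called genes were among the main calls.

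With DESeq2 the counts were 1073 (BAP10), 36 (BAP100), 875 (BAN500), 1516 (PHE100), 1693 (BAP100 against BAP10), 314 (BAP100 against PHE100) and 62 (BAN500 against BAP100). With limma voom and library weights they were 3230 (BAP10), 46 (BAP100), 822 (BAN500), 2236 (PHE100), 466 (CTE1500), 4426 (BAP100 against BAP10), 1327 (BAP100 against PHE100), 166 (BAN500 against BAP100) and 3901 (BAN500 against PHE100). With no filter on low values, and so more genes tested, they were 198 (BAP10), 15 (BAP100), 280 (BAN500), 128 (PHE100), 669 (CTE1500), 465 (BAP100 against BAP10) and 25 (BAP100 against PHE100).

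In limma fits to only the 2 groups compared, and so on fewer libraries, the counts were 0 for BAP10 (3553 at an unadjusted p under 0.05; DESeq2 and edgeR with TMM over all libraries called 1073 and 443), 2 (BAP100), 1427 (PHE100), 291 (CTE1500), 1826 (BAP100 against BAP10), 420 (BAP100 against PHE100) and 42 (BAN500 against BAP100). Without the AM250 group BAP100 against PHE100 gave 52.

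With the GC and length trends removed the counts were 206 (BAP10), 16 (BAP100), 823 (BAN500), 314 (BAP100 against BAP10) and 48 (BAP100 against PHE100). In AM250, GDF15 then turned to -0.08 (adjusted p = 0.78) and MDM2 to 0.38 (0.016), and CDKN1A in CTE1500 against AM250 to 0.59 (0.001). The share of called genes that were higher moved from 41.2% to 65.9% for BAN500 and from 40.2% to 61.6% for CTE1500.

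With the replicate number as a block the counts were 22 (BAP10), 297 (PHE100), 699 (BAP100 against BAP10) and 51 (BAP100 against PHE100). With the block and the GC and length trends removed they were 5 (BAP10), 697 (BAN500), 303 (PHE100), 178 (BAP100 against BAP10) and 43 (BAP100 against PHE100), GDF15 and MDM2 in AM250 were at -0.06 and 0.39, and CDKN1A in CTE1500 against AM250 at 0.59. The numbers did not pair the libraries: over 84 pairs with the same number, the mean correlation of deviations from the group means was -0.0119, and 8 of 29 libraries correlated best with their own number.

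With 1 library left out the counts ranged from 1 to 1843 (BAP10), 6 to 13 (BAP100), 245 to 613 (BAN500), 0 to 807 (PHE100; the count of 0 by limma had 3520 and 3454 genes at an unadjusted p under 0.05 without acetone replicate 4 and PHE100 replicate 1, and DESeq2 and edgeR with TMM over all libraries called 1516 and 665), 600 to 1957 (CTE1500), 7998 to 9080 (AM250), 105 to 1791 (BAP100 against BAP10), 3 to 179 (BAP100 against PHE100), 10 to 29 (BAN500 against BAP100), 1167 to 2342 (BAN500 against PHE100), 8766 to 9679 (CTE1500 against AM250) and 10292 to 11497 (any treatment).

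Of 2780 named-gene results with 1 library left out, 2313 kept their direction and side of the threshold and 461 lost the call. Of 319 named-gene results, 297 were kept with edgeR and RLE factors, 298 with edgeR and TMM, 297 with voom, 285 with the GC and length trends removed, 272 in fits to 2 groups, 271 with the block, 254 with no filter, 317 with TMM factors, and 319 with a pseudocount of 5 and with the values as deposited. DESeq2 kept 305 of 316. Of 98 list calls, 17 were kept with an estimated correlation.

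With the acetone libraries split so that none was shared, mean correlations over the splits with BAP10 were -0.01 (BAP100), 0.01 (BAN500), 0.06 (PHE100), -0.05 (CTE1500) and 0.16 (AM250). Those with BAP100 were 0.18 (BAN500), 0.11 (PHE100), 0.18 (CTE1500) and 0 (AM250), and those with BAN500 were 0 (PHE100), 0.34 (CTE1500) and -0.08 (AM250). PHE100 had 0.05 with CTE1500 and 0.07 with AM250, and CTE1500 had -0.04 with AM250.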

Other observations

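The 37 mitochondrial genes listed had 0 reads in any library, while nuclear pseudogenes of mitochondrial genes took 1.93% ± 0.539 of reads in AM250 (n = 4) and 0.982% ± 0.35 in acetone (n = 5). These pseudogenes share sequence with mitochondrial genes. Whether their reads came from nuclear or mitochondrial RNA therefore cannot be told, here or in the shares given above. MTCO1P12, a pseudogene of a cytochrome oxidase gene that was chosen after its values were seen, averaged 10700 CPM in AM250 and 5820 in acetone. The 10 highest genes took 5.6% of reads in AM250 and 4.31% in acetone.

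Some genes named in both BAN500 and CTE1500 for the size of their change are given as values only, since they were picked for it and both comparisons share the acetone libraries. MACROD2, ADGRL3 and SDK1 fell in both, by 10.3-fold, 8.83-fold and 5.3-fold in BAN500 and 9.38-fold, 7.12-fold and 5.07-fold in CTE1500, while H19, IL19 and PLA2G4E rose in both. H19 also rose in AM250 (11.3-fold).

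All tests of other splits of the libraries were planned. Up to 100 splits of the libraries into groups of the same sizes, or all 35 for 4 against 4, were counted, the real one included. For counts of genes, the share of splits was under 0.05 in each comparison, without adjustment over the comparisons. With so few splits no share below 1 of 100, or 1 of 35, could be reached. These shares therefore argue against chance without excluding it. For BAP10, 2 of 100 splits called as many genes (552 for the real split, and more, 749, for the highest other). For the other treatments 1 of 100, the real split, did: BAP100 (9, highest other 7), BAN500 (461, 289), PHE100 (771, 203), CTE1500 (1043, 822) and AM250 (9084, 7817). Between treatments it was 1 of 35: BAP100 against BAP10 (1112, 209), BAP100 against PHE100 (79, 0), BAN500 against BAP100 (15, 0), BAN500 against PHE100 (2204, 2) and CTE1500 against AM250 (9730, 5211). For any treatment it was 1 of 100 (11229, 2395).

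For the number of gene lists called by camera with the preset correlation, chance cannot be excluded in any comparison. As many lists were called in 96 of 100 splits for BAP10 (1 for the real split, 11 for the highest other), 39 for BAP100 (9, 15), 9 for BAN500 (13, 14), 65 for PHE100 (5, 13), 40 for CTE1500 (9, 13) and 19 for AM250 (10, 14). Of 35 splits it was 14 for BAP100 against BAP10 (6, 9), 3 for BAP100 against PHE100 (11, 13), 4 for BAN500 against BAP100 (12, 17), 9 for BAN500 against PHE100 (11, 15) and 5 for CTE1500 against AM250 (11, 14). For BAP10, 61 other splits called over 3 times the real number, which was 1 list, and whether a structure of the libraries other than the groups caused this was not tested. List calls that an estimated correlation did not keep may come from genes that vary together between libraries.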
